A study of Mus musculus with 17 samples.

How the data were processed

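RNA sequencing had been done on total RNA from mouse primordial germ cells that had been purified, in 17 samples, after removal of ribosomal RNA by hybridization and library preparation with the NEBNext Ultra II kit. The deposited values are FPKM computed by the authors, in 1 table for the 5 E11.5 libraries and 1 for the 12 E13.5 libraries, with 23361 genes each. The submitters' processing notes name the genome build mm10 and DESeq2. The aligner, the counting program and the gene annotation are not given in the sources used here. Genes are named by symbol; 100 entries of the E11.5 table carry joined symbols and 27 of the E13.5 table carry a number in place of a symbol. Coordinates are from GENCODE M21 on GRCm38 (mm10), in which 232 of 234 named genes were matched by symbol.

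Samples were grouped by embryonic day, sex and irradiation as their titles state. For the male E13.5 libraries, titles and condition entries disagree with the sample codes MIR and MC, so the code was used as the group. The cell type entry of irradiated female replicate 1 reads E11.5, whereas its title and source read E13.5, and its column stands in the E13.5 table. No columns were left without a sample, and no pair of libraries had identical values.

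Depth was estimated because no totals are given. FPKM values up to 0.3 were searched for whole multiples of each gene's smallest step. Within a tolerance of 0.1 fragments, 53.2% of 2942 low values at E11.5 and 86.5% of 7718 at E13.5 were whole multiples, where chance gives 20%. The estimates rest on 22 and 126 genes with transcripts of at least 3000 bases, cover counting error only, and could be off by any scaling factor in the deposited values. Over these genes the quartiles of the estimate were 54.7% and 109% of the median at E11.5, and 80.8% and 101% at E13.5.

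Tests used limma 3.58.1 in R 4.3.3 (limma-trend, empirical Bayes) on log2(FPKM + 1), and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 served for depth and figures. Genes with an FPKM of at least 1 in at least 2 libraries at E11.5, or 3 at E13.5, were tested. The 4 groups at E13.5 shared 1 fit. Adjusted p-values are Benjamini-Hochberg values, two-sided, with a threshold of 0.05. The 2 embryonic days were never tested against each other, since they stand in separate tables. The comparisons were E11.5 irradiated against non-irradiated, E13.5 female irradiated against non-irradiated, E13.5 male MIR against MC, female against male, and the difference between the female and male changes.

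There were 21 gene lists: p53 targets, apoptosis, G2/M, G1/S, DNA repair, pluripotency, germ cell, meiosis, female germ cell, male germ cell, histone, interferon, early stress, Sertoli, pregranulosa, Leydig, erythroid, endothelial, macrophage, mesenchyme and sex-check genes. Some genes stand in more than 1 list, such as Btg2 and Pmaip1. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01. No camera call held with an estimated correlation. Fry, whose p tests whether a list's genes move on balance in 1 direction and whose mixed p tests whether they move in either direction, was the other alternative; neither compares the list with other genes. The grouping, tests, lists and the alternatives named next, except those said to be added later, were chosen before the data were examined.

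Named genes were, in each comparison, the 10 largest rises and the 10 largest falls among called genes with no overlap between groups, without predicted and small RNA genes. Up to 4 called members of each list with the smallest adjusted p were added, as were 19 genes of the DNA damage, pluripotency and germ cell fields and the sex-check genes. Where no gene outside those exclusions passed, the 5 with the smallest p in each direction were named. Some genes that this rule names are not reported here. Other list members mentioned in the text, such as Amh and Sox9 in females, were chosen after their values were seen.

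Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at an FPKM of 5, quantile normalization, median scaling, library weights, robust moderation, the replicate number as a block, leaving out each library in turn, fitting only the groups compared, and exchanging the male codes. DESeq2 was not run because the tables hold FPKM and not counts. Chosen after seeing the data were the germ cell list level as a covariate, leaving out small RNA genes, and leaving out MIR replicates 1 and 3 together. The pipeline was tested on simulated data, in which 67 genes each with 1.5-fold and 2-fold changes and 66 with 4-fold changes were placed. In those runs, 11 of 113 calls at E11.5, 6 of 152 in the female, 4 of 146 in the male, 7 of 185 in the sex and 6 of 100 calls in the difference comparison were false.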

Results

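The data were RNA sequencing profiles of purified mouse primordial germ cells, the embryonic precursors of eggs and sperm, collected with or without exposure to ionizing radiation (IR). Of the 17 libraries, 5 came from E11.5 and 12 from E13.5 (E, embryonic day), when female germ cells approach meiosis and male germ cells approach mitotic arrest. The E11.5 libraries comprised 2 irradiated and 3 non-irradiated samples, with no sex given. The E13.5 libraries comprised 3 irradiated and 3 non-irradiated female samples and 2 male sets of 3, coded MIR and MC. The male labels conflict. Titles and condition entries call the MIR libraries non-irradiated and the MC libraries irradiated, whereas the codes, by the pattern of the female codes FIR and FC, read the other way. The male sets are therefore named by code, and male changes are given as MIR minus MC. The labels do not say whether replicates came from separate animals or litters, so p-values measure only the spread between these samples.

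Expression was given as FPKM (fragments per kilobase of transcript, scaled to library size) for 23361 genes in a table for each embryonic day. Library totals were not given. From the spacing of the lowest FPKM values, depth was estimated at 14.6 to 21 M fragments per E11.5 library and at 13.6 to 26.8 M per E13.5 library. The E11.5 estimate is rough, since over its 22 genes the quartiles were 54.7% and 109% of the median. Between 10805 and 11288 genes reached an FPKM of 1 in the E11.5 libraries, and between 10915 and 12487 in the E13.5 libraries. Genes simulated with a 2-fold difference were recovered in 47.8% of cases at E11.5, 79.1% in the female comparison, 80.6% in the male comparison, 95.5% between the sexes and 41.8% for the difference between the female and male changes. At 1.5-fold the recoveries were 8.96%, 40.3%, 34.3%, 71.6% and 7.46%. Fold changes below 2 were therefore often missed in the simulations, in which few genes changed. In the real E13.5 data many called genes changed by less than 2-fold. In females, for example, 1313 of 2807 rises and 87 of 2949 falls exceeded 2-fold. In a principal component analysis of the E13.5 libraries, the first component held 54.4% of the variance and the second 27.2%.

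The comparison of irradiated and non-irradiated germ cells at E11.5 addressed the response to DNA damage before sexual differentiation of the gonad. Several p53 target genes had higher means in the irradiated libraries without passing the test. Phlda3, a p53 target that restrains Akt signalling, was at 16.9 ± 1.33 FPKM (SD, n = 2) with IR and at 10.3 ± 0.589 (SD, n = 3) without. Plk2, a p53-induced kinase, was at 9.44 ± 2.36 and 3.49 ± 0.454 FPKM. Bbc3, which encodes the pro-apoptotic protein PUMA, was at 9.45 ± 2.61 and 4.62 ± 1.01 FPKM. Their log2 differences were 0.66, 1.20 and 0.89, each with an adjusted p of 0.974. Cdkn1a, the p21 inhibitor of the cell cycle, was at 21.3 ± 4.64 and 16.4 ± 2.33 FPKM, and Mdm2, the ubiquitin ligase that limits p53, was at 62.4 ± 8.31 and 53.8 ± 5.71 FPKM. The mean log2 level of the 41 measured p53 targets was 3.68 and 3.78 in the irradiated libraries and 3.55, 3.56 and 3.58 in the others.

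Of 11315 genes tested at E11.5, 1 rose and 1 fell. Both encode small nucleolar RNAs, which guide the chemical modification of other RNAs, and were named after their values were seen. Snord23 (GRCm38 chromosome 7, 15938762 to 15938870) was at 66.95 and 27.13 FPKM with IR and was listed at 0 in all 3 non-irradiated libraries (adjusted p = 0.00199). Snora5c (chromosome 11, 6620319 to 6620454) was listed at 0 in both irradiated libraries and was at 93.0, 51.4 and 86.6 FPKM in the others (adjusted p = 0.000143). The Snord23 call was lost when low values were not filtered (adjusted p = 0.196), and without irradiated replicate 1 or 2 the gene passed the filter in too few libraries to be tested. Among other genes with small p-values, Spint5 differed by 1.81 on the log2 scale and Hmgn5, a nucleosome-binding protein gene, by -1.11, each with an adjusted p of 0.602.

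None of the 41 p53 targets passed the test, and 1 rose when adjusted over the list alone. The camera set test, which compares a list with all other genes, placed the p53 list higher (adjusted p = 0.00173, and adjusted p = 0.464 with an estimated correlation). By the preset correlation it also placed germ cell genes (2.03e-06) and meiosis genes (0.0233) higher. It placed pluripotency genes (4.71e-05), histone genes (4.71e-05), G1/S genes (0.0236) and macrophage markers (0.0236) lower. For these 6 lists the adjusted p was 0.653 with an estimated correlation, and no member passed the test over all genes or over the list alone. Single libraries stood apart in some of these lists. The mean log2 level of histone genes was 3.32 in non-irradiated replicate 3 and 1.48 to 1.61 in the other 4 libraries, and that of macrophage markers was 3.18 in non-irradiated replicate 2 and 1.62 to 2.16 in the others. Irradiated replicate 1 was highest in germ cell genes (4.98, against 3.65 to 4.38) and meiosis genes (4.17, against 3.19 to 3.64), and lowest in pluripotency genes (6.22, against 6.52 to 6.76). Dazl, an RNA-binding protein gene needed for germ cell development, was at 412 FPKM there and at 12.4 to 92.6 in the other 4 libraries. The same library held the Sertoli markers Amh (8.18 FPKM, others at most 0.201), Cst9 (6.41, others at most 0.245), Ptgds (3.30) and Hsd17b3 (1.13), the last 2 listed at 0 elsewhere. The p53 target Pmaip1 was at 17.7 FPKM there and at most at 0.965 in the others, and Nanos2 was also highest there and at most at 0.0383 in the others. These 6 genes were chosen after their values were seen. Without irradiated replicate 2 the count of called genes was 17, and without non-irradiated replicate 2 or 3 it was 4. The other 12 lists tested had camera adjusted p-values from 0.0793 to 0.859, and pregranulosa and Leydig markers had too few measured members. At an unadjusted p under 0.05 there were 358 genes, and the groups did not overlap for 18.1% of genes, where chance gives 20%.

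**Figure D1:**
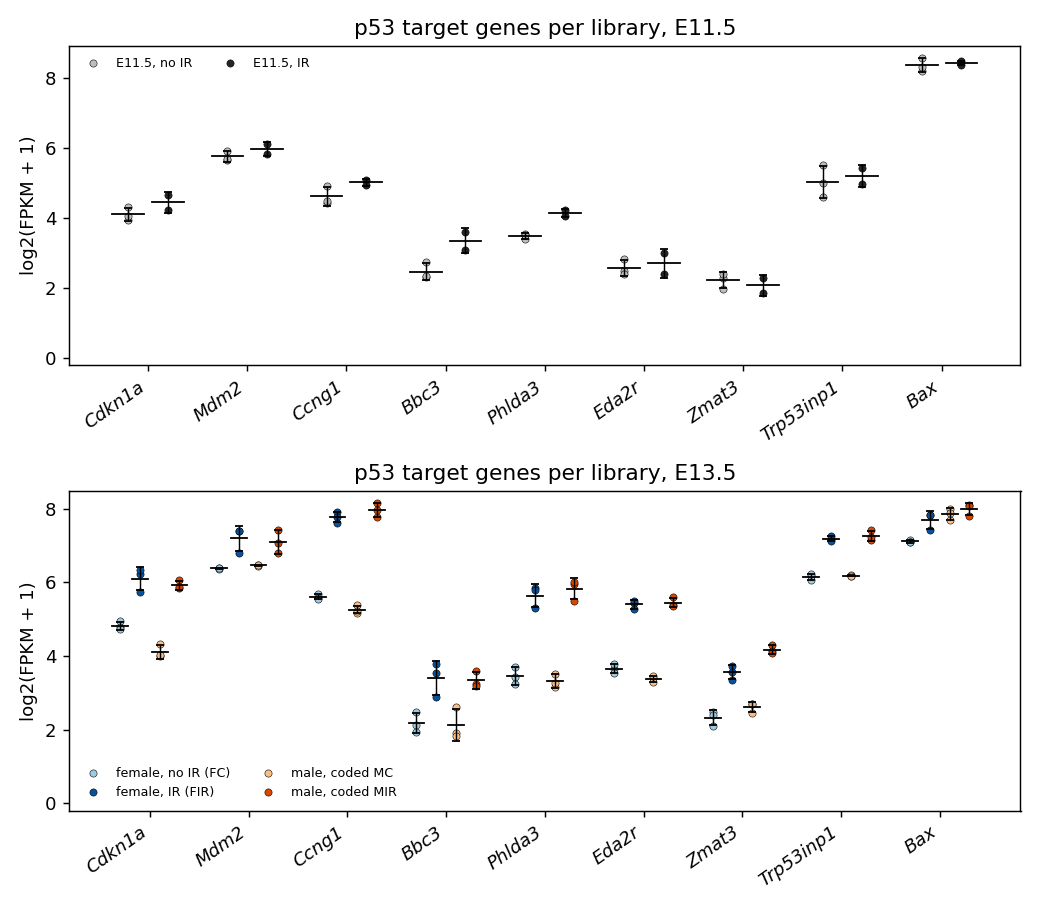
Levels of 9 p53 target genes in each library at E11.5 (top) and E13.5 (bottom), on the vertical axis as log2(FPKM + 1); dots are libraries, bars are group means and whiskers are SD. At E13.5, Ccng1 lies between 196.7 and 284.4 FPKM in the irradiated female and MIR libraries and between 35.3 and 50.9 in the other 6.

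The comparison of irradiated and non-irradiated female germ cells at E13.5 addressed the response to DNA damage around the onset of meiosis. The p53 target genes rose together. Ccng1 (chromosome 11, 40748552 to 40755311), the p53-induced cyclin G1, was at 217.7 ± 21 FPKM (SD, n = 3) with IR and 48.0 ± 2.50 (SD, n = 3) without, a log2 rise of 2.15 (SE 0.109). Cdkn1a (chromosome 17, 29090976 to 29100727) was at 68.9 ± 14.1 and 27.4 ± 2.09 FPKM, and rose by 1.28 (SE 0.146). Mdm2 (chromosome 10, 117688875 to 117710758) was at 148.8 ± 32.9 and 82.4 ± 1.04 FPKM, and rose by 0.82 (SE 0.167). Of 45 measured p53 targets, 38 rose and none fell, and adjusted over the list alone 38 rose and 1 fell. The median log2 change of the list was 1.06 (camera adjusted p = 7.88e-18, and adjusted p = 0.0617 with an estimated correlation), and the fry test, which does not compare with other genes, gave 6.51e-07. Other rises were 3.34 for Dcxr, 2.77 for Ephx1, a detoxifying epoxide hydrolase, 2.18 for Phlda3, 1.75 for Eda2r, a death-domain receptor, and 1.24 for Zmat3.

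Apoptosis genes moved mostly upward in the irradiated females. Of 29 measured, 14 rose and 4 fell, and adjusted over the list alone 14 rose and 5 fell (camera adjusted p = 0.00961, and adjusted p = 0.406 with an estimated correlation). Without non-irradiated replicate 1 or 3, 2 fell. Pmaip1, which encodes the BH3-only protein NOXA, rose by 1.44 on the log2 scale and Bbc3 by 1.22. Fas, a death receptor, rose by 1.87, Bak1, a pore-forming effector of mitochondrial apoptosis, by 1.88, and Apaf1, the apoptosome scaffold, by 1.08. Bax rose by 0.58 (adjusted p = 0.00299).

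Genes of the cell cycle and of DNA repair fell in the irradiated females. Of 38 G2/M genes, 31 fell and none rose, over all genes and adjusted over the list alone, with a median log2 change of -0.68. Racgap1, a regulator of cytokinesis, fell by 0.82, Ncapd2, a condensin subunit, by 0.90 and Ect2 by 0.90. Of 41 G1/S genes, 25 fell, and 27 adjusted over the list alone. Mcm10, a DNA replication factor, fell by 0.88. Of 45 DNA repair genes, 27 fell and 2 rose, and adjusted over the list alone 30 fell and 2 rose. Without irradiated replicate 1, 4 repair genes rose. Atm, the kinase that senses double-strand breaks, fell by 0.71, whereas Rad51d, a homologous recombination gene, rose by 0.97. The camera adjusted p-values of the G2/M, G1/S and repair lists were 9.18e-11, 6.04e-07 and 3.21e-05. For G2/M the adjusted p was 0.406 with an estimated correlation, and for G1/S and repair the adjusted p was 0.51 with an estimated correlation. With the level of germ cell genes as a covariate, 19 G2/M, 2 G1/S and 10 repair genes fell.

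Pluripotency and germ cell genes also fell. Nanog (chromosome 6, 122707489 to 122714633), a pluripotency transcription factor, was at 33.3 ± 0.797 FPKM with IR and 78.7 ± 6.35 without (SD, n = 3 each), and fell by 1.21 on the log2 scale. Of 29 pluripotency genes, 19 fell and 1 rose, and adjusted over the list alone 21 fell and 1 rose, the latter not without non-irradiated replicate 1 (camera adjusted p = 1.85e-06, and adjusted p = 0.51 with an estimated correlation). Fbxo15 fell by 1.33 and Esrrb, a nuclear receptor, by 1.29. Pou5f1, which encodes OCT4, was at 442.5 ± 82.8 and 649.2 ± 22.2 FPKM and did not pass (adjusted p = 0.0533), but passed with library weights (0.000635), with the replicate block (0.0487), without small RNA genes (0.0499) and with only the groups compared (0.0121). Of 25 germ cell genes, 13 fell, and 14 adjusted over the list alone (camera adjusted p = 0.000223, and adjusted p = 0.51 with an estimated correlation). Dnd1, an RNA-binding protein gene that protects germ cells from loss, fell by 1.40. The germ cell count was 4 without irradiated replicate 1, 7 without non-irradiated replicate 1, and 5 without non-irradiated replicate 2 or 3, and it was 8 under quantile normalization or without a filter. Dazl fell by 0.63 and Ddx4, the germ cell RNA helicase, by 0.65. The Dazl call was lost without irradiated replicate 1 (adjusted p = 0.148) or non-irradiated replicate 1 (0.0634), 2 (0.0781) or 3 (0.109), under quantile normalization (0.111) and without a filter (0.0668), and the Ddx4 call without irradiated replicate 1 (0.0775) or non-irradiated replicate 3 (0.0593).

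Most meiosis genes had lower means in the irradiated females, and few passed the test. Stra8, which licenses meiotic entry, was at 82.8 ± 39.4 FPKM with IR and 90.5 ± 33.5 without (SD, n = 3 each; adjusted p = 0.693). Sycp3, a synaptonemal complex component, was at 157.3 ± 49.2 and 193.0 ± 37.9 FPKM (adjusted p = 0.374). Rec8, the meiotic cohesin, rose by 0.57 (adjusted p = 0.0271), a call lost without irradiated replicate 2 (0.0678) or 3 (0.0904) or non-irradiated replicate 1 (0.128), when no meiosis gene rose by limma. Of 33 meiosis genes, 6 fell and 1 rose, and adjusted over the list alone 5 fell and none rose by limma, with a median log2 change of -0.41 and 4 members above 0 (camera adjusted p = 0.0163, and adjusted p = 0.585 with an estimated correlation). The number that fell was 2 without irradiated replicate 1 and 3 without non-irradiated replicate 2. Of 17 female germ cell genes, 7 fell (camera adjusted p = 0.113), or 3 without irradiated replicate 1. Of 22 male germ cell genes 8 fell and 4 rose, with a median log2 change of -0.34 and a mean of 0.023 (camera adjusted p = 0.445), and 2 rose without non-irradiated replicate 2 or 3. Those that rose included the cell cycle inhibitors Cdkn1b, by 2.75, and Cdkn1c, by 2.52. Somatic cell markers rose in the same libraries, as given next, so the cells behind these rises cannot be told.

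Markers of gonadal somatic cells were higher in the same irradiated female libraries. Fst (chromosome 13, 114452290 to 114458951), which encodes the pregranulosa protein follistatin, was at 99.6, 40.1 and 35.5 FPKM with IR and at no more than 2.02 without, a log2 rise of 4.27. Of 12 pregranulosa markers, 10 rose, with a median log2 change of 2.81 (camera adjusted p = 2.53e-08, and adjusted p = 0.366 with an estimated correlation). Wnt4, a signal for ovarian development, rose by 3.44. Of 17 Sertoli markers, 7 rose, or 11 with a pseudocount of 0.1 or library weights (camera adjusted p = 0.000441, and adjusted p = 0.51 with an estimated correlation). These included Wt1, Gata4 and Nr5a1, transcription factors active in supporting cells of both sexes, which rose by 3.84, 3.78 and 3.72, whereas Sox9 and Amh, which mark Sertoli cells, did not pass (adjusted p = 0.0958 and 0.635). All 9 macrophage markers rose (camera adjusted p = 3.21e-05, and adjusted p = 0.406 with an estimated correlation). Of 14 mesenchyme markers, 8 rose and 1 fell (camera adjusted p = 0.00204, and adjusted p = 0.406 with an estimated correlation), and 4 rose under quantile normalization, 13 with library weights, 2 of 5 with a filter at an FPKM of 5 and 5 of 11 without irradiated replicate 2, while none fell by limma without non-irradiated replicate 1. The counts for the pregranulosa, Sertoli, macrophage and mesenchyme lists were identical when adjusted over the list alone. Xist, the RNA that silences an X chromosome, was at 83.4, 23.1 and 13.8 FPKM with IR and at 1.20 to 2.35 without. The largest rise among all genes named was that of Cst8, by 4.95, and Kitl, the ligand of the Kit receptor on germ cells, rose by 4.37.

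Immediate early and stress genes rose as well, with 9 of 21 higher and 1 lower, over all genes and adjusted over the list alone, and 17 higher with library weights (camera adjusted p = 0.00071, and adjusted p = 0.51 with an estimated correlation). Btg2, an antiproliferative p53 target, rose by 2.78, and Gadd45g, a stress sensor, by 2.24. The embryonic globin gene Hbb-y fell by 3.73 and Slc2a3, a glucose transporter gene, by 1.42. Leydig markers (3 of 6 rose), endothelial markers (3 of 6 rose) and erythroid markers (2 of 6 fell) each had a camera adjusted p of 0.233. Interferon genes (2 of 7 rose, 1 fell) and sex-check genes (1 of 5 rose) each had 0.447, and histone genes (1 of 18 rose) had 0.818. In all, 2807 genes rose and 2949 fell among 12852 tested, and 1313 of the rises and 87 of the falls exceeded 2-fold. Under quantile normalization 2226 rose and 3132 fell, and under median scaling 2583 rose and 3331 fell. The groups did not overlap for 61.6% of genes, where chance gives 10%. With the level of germ cell genes as a covariate, 3095 genes were called and 39 p53 targets rose.

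**Figure D2:**
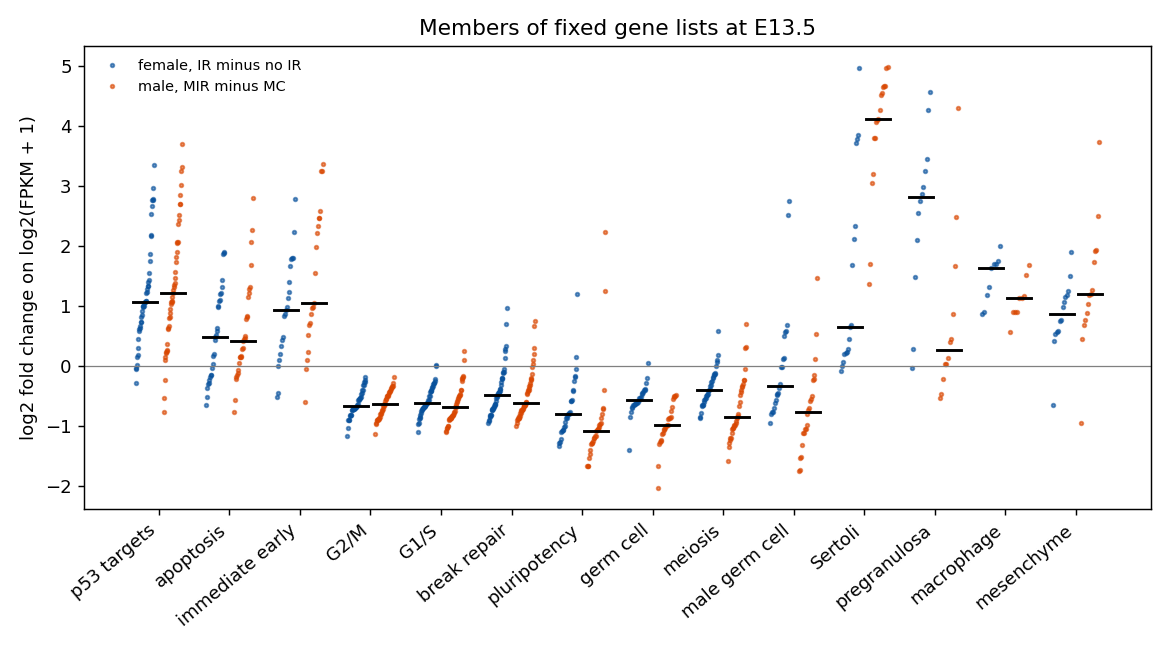
Log2 fold changes of the measured members of 14 gene lists at E13.5, for irradiated against non-irradiated females and for males coded MIR against MC; dots are genes and black bars are medians. The p53 targets have medians of 1.06 and 1.22, and the Sertoli markers have medians of 0.64 and 4.12.

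The comparison of the male sets at E13.5 addressed the same response in germ cells before mitotic arrest, with its direction left to the codes. The p53 target genes were higher in the libraries coded MIR. Ccng1 was at 250.1 ± 33.2 FPKM (SD, n = 3) in MIR and 37.5 ± 2.88 (SD, n = 3) in MC, a log2 rise of 2.70 (SE 0.109). Cdkn1a was at 59.9 ± 5.03 and 16.4 ± 2.30 FPKM, a rise of 1.81 (SE 0.146), and Mdm2 was at 138.0 ± 31.2 and 87.5 ± 1.20 FPKM, a rise of 0.63 (SE 0.167; adjusted p = 0.00649). The Mdm2 call was lost under median scaling (adjusted p = 0.0585). Of 45 p53 targets, 36 rose and 2 fell, over all genes and adjusted over the list alone. Their median log2 change was 1.22 (camera adjusted p = 1.41e-13, and adjusted p = 0.133 with an estimated correlation). Dcxr rose by 3.70, Ephx1 by 2.70, Phlda3 by 2.50 and Eda2r by 2.07. Pmaip1 (chromosome 18, 66458533 to 66465565) fell by 0.78 (adjusted p = 0.0419), a call lost without MIR replicate 1 (0.197) or MC replicate 2 (0.115) or 3 (0.137), with a pseudocount of 0.1 (0.0524), without a filter (0.0747), under quantile normalization (0.0961) and with only the groups compared (0.0585). The number of p53 targets that fell was 1 without any of those 3 libraries.

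Of 29 apoptosis genes, 14 rose and 2 fell in MIR, over all genes and adjusted over the list alone (camera adjusted p = 0.00355, and adjusted p = 0.416 with an estimated correlation). Without MIR replicate 1, MC replicate 2 or MC replicate 3, 1 fell. Casp8, the initiator caspase of death receptors, rose by 2.79, Fas by 2.06, Bbc3 by 1.22 and Apaf1 by 1.14. Bax was at 255.7 ± 26.7 and 232.1 ± 25.3 FPKM (SD, n = 3 each; adjusted p = 0.353), and passed under quantile normalization (adjusted p = 0.0027). Without MIR replicates 1 and 3, which had the highest Sertoli marker levels, 7 apoptosis genes rose.

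Cell cycle and repair genes were lower in MIR. Of 38 G2/M genes 33 fell, and 35 adjusted over the list alone, with none higher and a median log2 change of -0.64. Plk1, a mitotic kinase, fell by 0.79 and Ncapd2 by 0.90. Of 41 G1/S genes, 33 fell, also when adjusted over the list alone, among them Mcm6, a subunit of the replicative helicase, by 1.03. Of 45 repair genes, 31 fell and 2 rose, also when adjusted over the list alone. Bard1, the partner of BRCA1, fell by 0.95 and Rad51d rose by 0.75, the latter not under quantile normalization (adjusted p = 0.256). The number of repair genes that rose was 1 without MIR replicate 1 or 3 or MC replicate 2 or 3. The camera adjusted p-values for G2/M, G1/S and repair were 2.79e-08, 2.01e-06 and 4.53e-05. For these lists, in the same order, the adjusted p was 0.452, 0.489 and 0.453 with an estimated correlation. Without MIR replicates 1 and 3 together, 13 G2/M, 6 G1/S and 5 repair genes fell, and with the level of germ cell genes as a covariate 1, 0 and 1 fell by limma.

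Pluripotency, germ cell, meiosis and male germ cell genes were lower in MIR too. Nanog was at 40.1 ± 12.5 FPKM in MIR and 93.8 ± 2.91 in MC (SD, n = 3 each), and fell by 1.25, while Pou5f1 fell by 1.06. Of 29 pluripotency genes 26 fell and 2 rose (camera adjusted p = 2.51e-07). Of 25 germ cell genes 21 fell (1.6e-06), including Dnd1 by 2.03, Dazl by 1.07 and Ddx4 by 1.01. Of 22 male germ cell genes 16 fell and 1 rose (0.000611). Among these, Nanos2, a regulator of the male germ cell fate, fell by 1.52, and Lefty1 (chromosome 1, 180935022 to 180938400) and Lefty2, inhibitors of Nodal signalling, by 1.33 and 1.73. For the pluripotency, germ cell and male germ cell lists the adjusted p was 0.452 with an estimated correlation. Of 33 meiosis genes 20 fell and 1 rose (camera adjusted p = 0.000327, and adjusted p = 0.503 with an estimated correlation). Adjusted over the list alone, the falls were 26, 21, 16 and 20, in the order given, and 2 male germ cell genes rose. Without MIR replicate 2, 2 male germ cell genes also rose over all genes. Without MIR replicates 1 and 3, 18 pluripotency, 6 germ cell, 4 meiosis and 8 male germ cell genes fell, and with the germ cell covariate 3 pluripotency genes fell.

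Sertoli cell markers were higher in MIR. Amh (chromosome 10, 80805243 to 80807648), the anti-Müllerian hormone made by Sertoli cells, was at 846.2, 252.1 and 876.2 FPKM in MIR replicates 1 to 3 and at 15.1, 28.0 and 24.8 in MC. All 17 Sertoli markers rose, also when adjusted over the list alone, with a median log2 change of 4.12 (camera adjusted p = 2.64e-11, and adjusted p = 0.416 with an estimated correlation). Dhh, a Sertoli cell signal, rose by 4.55 and Sox9, the testis-determining transcription factor, by 3.04. Of 14 mesenchyme markers 11 rose and 1 fell, and adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 0.00083, and adjusted p = 0.416 with an estimated correlation), and 7 of 12 rose without MIR replicate 2 and 6 under quantile normalization or with library weights. Of 9 macrophage markers 8 rose, also when adjusted over the list alone, and 4 under quantile normalization (camera adjusted p = 0.00247, and adjusted p = 0.452 with an estimated correlation), and of 6 Leydig markers 4 rose (camera adjusted p = 0.0282, and adjusted p = 0.452 with an estimated correlation). MIR replicate 2 had the lowest Amh of the 3 and the highest Mdm2, at 171.5 FPKM against 109.8 and 132.8. Of 21 stress genes 15 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 8.48e-05, and adjusted p = 0.452 with an estimated correlation). Their mean log2 level was 4.72 in MIR replicate 3, 3.68 and 3.73 in MIR replicates 1 and 2 and 2.56 to 2.59 in MC. Among them Egr1, an immediate early transcription factor gene, rose by 3.37 and Btg2 by 3.24.

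The lists that camera did not call in the male comparison were pregranulosa markers (4 of 12 rose; adjusted p = 0.151), endothelial markers (3 of 6 rose, 1 fell; 0.286) and erythroid markers (1 of 6 rose; 0.542). They also included female germ cell genes (5 of 17 rose, 7 fell; 0.446), with a median of -0.23 and a mean of 0.054, and histone (1 of 18 rose, 2 fell; 0.48), interferon (1 of 7 rose, 3 fell; 0.542) and sex-check genes (2 of 5 rose, 1 fell; 0.424). In all, 3690 genes rose and 3989 fell among 12852 tested, with 1882 rises and 401 falls beyond 2-fold. The groups did not overlap for 64.9% of genes, where chance gives 10%. Median scaling moved the median log2 change of all genes from -0.042 to -0.203, with 3076 genes higher and 5143 lower (37.4% higher against 48.1%). Without MIR replicates 1 and 3, 3271 genes were called and 32 of 44 p53 targets rose, and with the germ cell covariate 1274 genes were called and 34 p53 targets rose. Of the genes that rose in irradiated females, 2101 also rose in MIR, where independence would give 806, and of those that fell 2323 also fell, where it would give 915. Genes called in opposite directions numbered 29 and 30. Across genes, which are not independent replicates, the changes correlated with a Pearson r of 0.739.

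**Figure D3:**
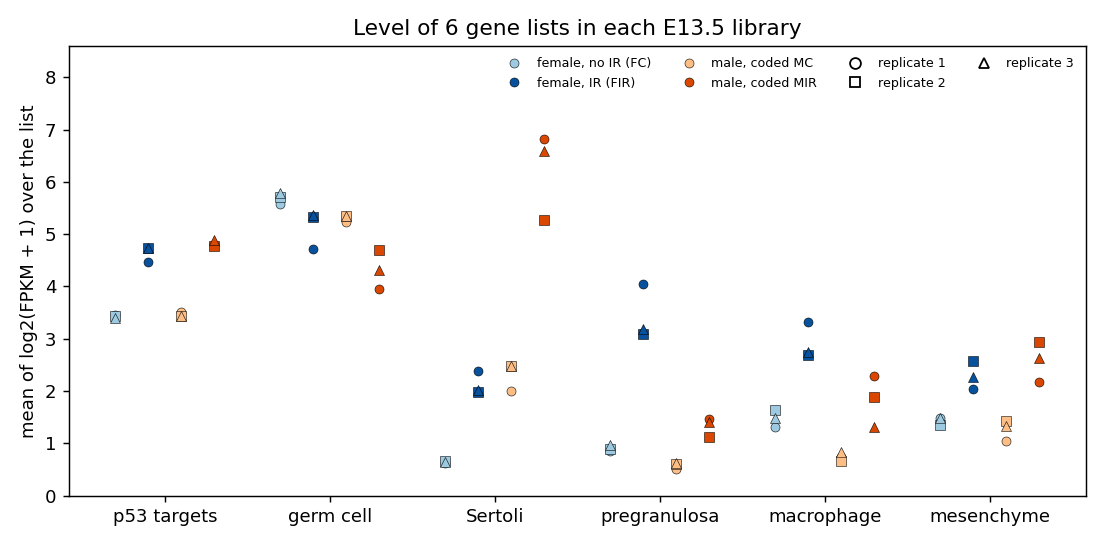
Mean log2(FPKM + 1) of 6 gene lists in each E13.5 library, with symbols for replicates. The p53 target level lies between 4.47 and 4.88 in the irradiated female and MIR libraries and between 3.39 and 3.52 in the other 6.

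The comparison of the sexes at E13.5, over the mean of both sets of each sex, described germ cells at the point where their paths part. Stra8 (chromosome 6, 34920163 to 34939344) was at 82.8 ± 39.4 and 90.5 ± 33.5 FPKM in the female groups and at 0.263 ± 0.0460 and 0.706 ± 0.377 in MIR and MC (SD, n = 3 each), a log2 difference of 5.81 (SE 0.256). Phlda2 (chromosome 7, 143501545 to 143503150), an imprinted gene, was higher in females by 6.08 (SE 0.131). Of 33 meiosis genes, 28 were higher in females and none lower, and 29 were higher when adjusted over the list alone (camera adjusted p = 7.85e-11, and adjusted p = 0.385 with an estimated correlation). Rec8 differed by 3.70, Sycp3 by 1.66 and Msh4, a crossover gene, by 1.27. Of 17 female germ cell genes 13 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 7.56e-07, and adjusted p = 0.144 with an estimated correlation), including Gata2 by 3.78, Nr6a1 by 2.56 and Msx1 by 2.05. With the germ cell covariate, 13 meiosis genes were higher.

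Some male germ cell genes and Y-linked genes were higher in the male libraries. Lefty2 was lower in females by -5.60 on the log2 scale, Lefty1 by -4.89, and Tdgf1, the Nodal co-receptor, by -3.28. Nanos2 differed by -1.33. Of 22 male germ cell genes, 11 were lower and 7 higher in females, also when adjusted over the list alone (camera adjusted p = 0.164). Pmaip1 was lower in females by -2.88. The Y-linked gene Eif2s3y differed by -6.93, and Uty and Kdm5d were listed at 0 in all 6 female libraries. Of the 5 sex-check genes, 4 were lower and 1 higher in females (camera adjusted p = 0.00036, and adjusted p = 0.114 with an estimated correlation).

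Somatic markers also differed between the sexes. Of 17 Sertoli markers 15 were lower in females, among them Amh by -6.68 and Cst9 by -6.58 (camera adjusted p = 2.05e-09, and adjusted p = 0.372 with an estimated correlation). Of 12 pregranulosa markers 10 were higher and 1 lower (camera adjusted p = 1.96e-05, and adjusted p = 0.372 with an estimated correlation), and 6 of the 9 still measured were higher without irradiated female replicate 2 or 3. All 9 macrophage markers were higher in females (camera adjusted p = 0.000366, and adjusted p = 0.489 with an estimated correlation). The counts for these 3 lists were identical when adjusted over the list alone. Of 25 germ cell genes 14 were higher and 1 lower, and 17 were higher when adjusted over the list alone (camera adjusted p = 3.53e-05, and adjusted p = 0.724 with an estimated correlation). Of 18 histone genes 9 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.00711, and adjusted p = 0.144 with an estimated correlation). The p53 list was not called (8 higher and 12 lower of 45; camera adjusted p = 0.717), with 5 higher without irradiated female replicate 2, non-irradiated female replicate 1 or MC replicate 2. The other 11 lists without a call had camera adjusted p-values from 0.353 to 0.717. In all, 2886 genes were higher and 3524 lower in females among 12852 tested (3269 and 2809 under median scaling, 3162 and 3029 under quantile normalization), and every female library lay apart from every male library for 13% of genes. The chance share of 10% given above holds for 3 against 3 libraries and is lower for these larger groups.

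**Figure D4:**
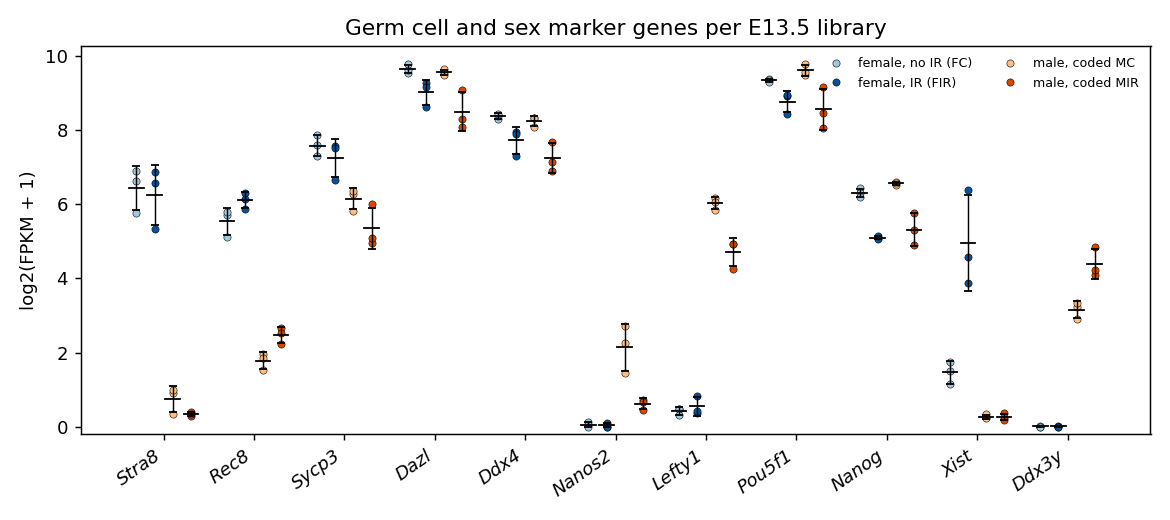
Levels of 11 germ cell, pluripotency and sex-linked genes in each E13.5 library, on the vertical axis as log2(FPKM + 1); dots are libraries. Stra8 and Rec8 are higher in the 6 female libraries than in the 6 male libraries, and Ddx3y is higher in the male libraries.

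The last comparison asked where the female change (irradiated minus non-irradiated) differed from the male change (MIR minus MC). Supporting cell markers, most of which differ between the sexes in level as given above, were among the genes that differed. Fst differed by 4.80 on the log2 scale (SE 0.413), higher in the female change, and Amh by -4.41 (SE 0.538), higher in the male change. Of 12 pregranulosa markers 8 differed toward females, also when adjusted over the list alone (camera adjusted p = 1.23e-07, and adjusted p = 0.485 with an estimated correlation), and 5 of the 9 still measured did so without any 1 of the 3 irradiated female libraries. Of 17 Sertoli markers 11 differed toward males, and 12 adjusted over the list alone (camera adjusted p = 8.84e-11, and adjusted p = 0.485 with an estimated correlation). A fall in MIR alone can also give a difference toward females. Of 22 male germ cell genes 7 differed toward females, and 8 adjusted over the list alone (camera adjusted p = 4.93e-05, and adjusted p = 0.485 with an estimated correlation). That count was 11 without MIR replicate 2 and 4 without MC replicate 3, and it was 3 under quantile normalization and 11 with library weights.

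Among p53 targets, 4 of 45 differed between the sexes. Pmaip1 differed by 2.21 and Sesn2, a stress-induced metabolic regulator, by 0.73, whereas Perp, an effector of p53-dependent death, differed by -1.36 and Ercc5, a nucleotide excision repair nuclease gene, by -0.97. Adjusted over the list alone, 2 differed toward females and 3 toward males (camera adjusted p = 0.124). The number toward males was 5 without MIR replicate 2, and 1 without MC replicate 3 or non-irradiated female replicate 1. The Perp call was lost without MC replicate 3 (adjusted p = 0.051) or non-irradiated female replicate 1 (0.0518) and under quantile normalization (0.0519), and the Pmaip1 call under quantile normalization (0.0531). Ccng1 differed by -0.54 (adjusted p = 0.0507), and passed without MIR replicate 2 (0.00858) or irradiated female replicate 1 (0.0309), with library weights (0.00236), with the replicate block (0.0222) and without small RNA genes (0.0487). No G2/M, G1/S or repair gene differed by limma, over all genes or over the list alone. Of all 12852 genes 998 did, and 3041 had an unadjusted p under 0.05. Only 7.46% of simulated 1.5-fold differences were recovered in this comparison, so small differences in these lists could be missed.

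Camera also called the pluripotency (0.029), germ cell (0.00229), meiosis (0.0181) and erythroid (0.0456) lists. With an estimated correlation the adjusted p was 0.829 for the first 3 and 0.816 for the erythroid list. The other 13 lists without a call had camera adjusted p-values from 0.0659 to 0.962. In all, 998 genes passed, 361 toward females and 637 toward males. The count was 508 without MIR replicate 1, 2490 without MIR replicate 2 and 463 without MIR replicate 3. It was 646, 641 and 559 without MC replicates 1, 2 and 3, and 598 and 636 without irradiated female replicates 2 and 3. Without non-irradiated female replicates 1, 2 and 3 it was 552, 545 and 522. Without MIR replicates 1 and 3 together it was 198. If MC is taken as the irradiated male set, as titles and condition entries state, 8702 genes differed, 4187 toward females and 4515 toward males, including 39 p53 targets toward females.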

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

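The tests of the 3 patterns weighed below were chosen after the results were seen, whereas the tests on other splits of the samples were not. The results listed here stand out because the change in females (irradiated minus non-irradiated) differed from the change in males (MIR minus MC) by a test of the difference itself, in 998 genes, 7 lists and 44 named genes. A gene hardly expressed in 1 sex may differ here only because it had little to change there. The mean log2 level of Sertoli markers was 0.633 to 0.667 in non-irradiated females, and that of pregranulosa markers was 0.502 to 0.618 in MC. For Ddx3y and Hsd17b3 the difference kept its size with the male codes turned (1.229 and 4.656), so only the male change entered it. Such differences do not show a response particular to 1 sex.

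Genes of the Sertoli list differed toward the male change. On the log2 scale the differences were -4.66 for Hsd17b3, which makes testosterone, -4.41 for Amh, -4.37 for Ptgds, -4.35 for Aard, -4.10 for Dhh, -3.83 for Col9a3 and -3.13 for Cbln4. Genes outside that list on this side were Tesc (-4.62), AU015836 (-4.33), Cited1 (-3.89), Nt5e (-3.83), Cyp26b1, which degrades retinoic acid (-3.02), Id1 (-2.52), Vim (-2.24), Alas2 (-2.16), Postn (-1.76), Id2 (-1.54), Perp (-1.36), Hist1h1c (-1.26), Ddx3y (-1.23), Fut4 (-1.10), Ercc5 (-0.97), Scarb1 (-0.61) and Xiap (-0.57).

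Pregranulosa genes differed toward the female change, with 4.80 for Fst, 3.44 for Rspo1, 3.12 for Irx3 and 2.83 for Foxl2, a determinant of ovarian fate. With them stood Defb7 (3.80), Xist (3.51), Gng13 (3.48), Enpp2 (3.40), Mest (3.27), Cdkn1b (2.90), Pmaip1 (2.21) and Bnc2 (1.88). Male germ cell genes stood there too, with Nanos2 (1.5), Lefty1 (1.45) and Nodal (1.15), beside Pou6f1 (1.22), Ifitm1 (1.11), Isg15 (1.09), Hist1h3c (0.92) and Sesn2 (0.73). With the male codes turned, the differences were -1.545 for Nanos2 and -1.202 for Lefty1. For these genes the difference therefore came mostly from their falls in MIR, where germ cell genes were lower too, and not from a rise in females. The camera adjusted p-values were 8.84e-11 for Sertoli, 1.23e-07 for pregranulosa, 4.93e-05 for male germ cell, 0.00229 for germ cell, 0.0181 for meiosis, 0.029 for pluripotency and 0.0456 for erythroid genes. No list passed with an estimated correlation.

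Of the 44 genes, 8 lost their call when 1 library was left out, here given by code (FIR and FC for irradiated and non-irradiated females) and replicate number, followed by the adjusted p without it. The Fut4 call was lost without MIR 1 0.0529, MIR 3 0.0595, MC 1 0.0522, MC 3 0.0568, FIR 2 0.0501, FC 2 0.061 or FC 3 0.0623. The Scarb1 call was lost without MIR 1 0.0655, MIR 3 0.0767, MC 1 0.0585, MC 2 0.0579, MC 3 0.0694, FIR 2 0.0595, FIR 3 0.0519, FC 1 0.0816 or FC 2 0.0696. The Xiap call was lost without MIR 1 0.104, MIR 3 0.0707, MC 1 0.0943, MC 3 0.107, FIR 2 0.0972, FIR 3 0.0977, FC 1 0.106, FC 2 0.0522 or FC 3 0.118. The Hist1h3c call was lost without MIR 1 0.064, MIR 3 0.124, MC 1 0.0715, MC 3 0.0628, FIR 2 0.0901, FIR 3 0.108, FC 1 0.103, FC 2 0.0943 or FC 3 0.109. The Isg15 call was lost without MIR 1 0.0716, MIR 3 0.0809, MC 2 0.0579, MC 3 0.0773, FC 1 0.0538, FC 2 0.0685 or FC 3 0.0776. The Nanos2 call was lost without MIR 1 0.0639, MIR 3 0.0585, FIR 2 0.058, FC 1 0.0524, FC 2 0.0596 or FC 3 0.0652. The Alas2 call was lost without MC 1 0.0584, FIR 2 0.0502 or FC 3 0.0651. The Perp call was lost without MC 3 0.051 or FC 1 0.0518.

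Among 100 of 200 splits of the samples by sex, 5, the real one included, gave as many genes as the 998, and the highest other gave 2231. The splits exchanged the sexes separately within FIR and MIR and within FC and MC. Some therefore carried part of the female against male difference into this count. They cannot decide whether chance gave the 998, and chance is not excluded for that count. For female against male, 1 of 100 splits, the real one, gave as many genes as the 6410, with 1584 as the highest other. This argues against chance for that count, as far as the libraries are independent samples, which the labels do not say. For irradiation in females (5756 genes) and MIR against MC (7679 genes), 1 of 10 splits gave as many, the highest other being 0 in each. Such 10 splits are too few for a share under 0.05.

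The first pattern weighed is the p53 target rise in MIR. Of 45 targets, 36 rose, and an exchange of the irradiation entries of the male libraries, with the codes right, is a candidate explanation. The mean log2 level of the targets was 4.77 to 4.88 in MIR and 3.44 to 3.52 in MC. It was 4.47 to 4.74 in irradiated and 3.39 to 3.45 in non-irradiated females. MC thus lay near the non-irradiated females. This argues against MC as the irradiated set, as far as the sexes respond alike. RNA of 1 somatic cell type as the only source would raise p53 targets with its markers. Within the irradiated female and MIR libraries the slopes were negative for supporting cells (-0.355, and -0.878 to -0.0828 without 1 library), macrophages (-0.538, -1.17 to -0.241) and Leydig cells (-1.06, -6.22 to -0.471), also with mean log2 levels. Their exact permutation p-values, which test for any relation, were 0.139, 0.0278 (the smallest possible) and 0.222. Adjusted over 6 relations they were 0.208, 0.167 and 0.267. The negative slopes lean against these cell types as the only source, but 6 libraries do not settle it. Endothelial cells (1.16, 0.487 to 1.46, exact permutation p = 0.111, with r = 0.883, or 0.081 without the 2 farthest libraries) and mesenchyme cells (-0.531 with mean FPKM but 0.905 with mean log2 levels) cannot be told apart from the germ cells as the source, because the p missed 0.05 for the former and the measures differed for the latter. Irradiation of the MIR set and several somatic cell types together stay open, the latter not tested directly. With the germ cell list level as a covariate, the genes called in MIR against MC went from 7679 to 1274, whereas most p53 targets still rose, as given above. Their rise thus depended less on that level than most other calls did. Whether a lower share of germ cell RNA was its whole cause cannot be decided this way, even if the list tracks that share. The germ cell level did not overlap between MIR (3.96 to 4.69) and MC (5.23 to 5.35), so the covariate had to be carried across a gap.

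The second pattern is the rise of supporting cell markers. Scaling between libraries is argued against by all 17 Sertoli markers rising in MIR under median scaling and under quantile normalization. For MIR, a lower share of germ cells with the other cell types in unchanged proportions is argued against by Tek, with 1.59 the highest endothelial rise, beside a Sertoli median of 4.12. The same test was not run for the irradiated females. More supporting cells among the purified cells may explain it. Marker and germ cell levels correlated at r = -0.976 in 6 libraries (exact permutation p = 0.0556, where 0.0278 is the smallest possible, and adjusted p = 0.167 over 6 relations). The p missed 0.05. A response of the cells themselves that raised the markers and lowered germ cell genes would give such a correlation too. More supporting cells therefore cannot be told apart from such a response by this relation.

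The third pattern is the fall of cell cycle genes. With the germ cell list level as a covariate, the G1/S genes called lower went from 25 to 2 in females (median -0.62 to -0.12, median SE 0.187 to 0.137) and from 33 to 0 in MIR by limma (-0.69 to 0.074, SE 0.187 to 0.19). G2/M genes went from 33 to 1 in MIR (-0.64 to -0.18, SE 0.138 to 0.171), so these calls ended because the changes shrank, and a lower share of germ cell RNA may explain them. In females 19 of the 31 G2/M genes were called lower in both fits (-0.68 to -0.38, SE 0.138 to 0.122). The covariate cannot decide whether a lower share was the whole cause, because the germ cell list level did not overlap between the groups compared. It was 4.71 to 5.37 in FIR and 5.58 to 5.79 in FC, and 3.96 to 4.69 in MIR and 5.23 to 5.35 in MC. The relation within groups had to be carried across that gap. A response to irradiation stays open in all 4 cases, because the germ cell list may itself respond.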

How the results depend on the processing

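The germ cell covariate, the removal of small RNA genes and the removal of MIR replicates 1 and 3 together were chosen after the data were seen. At E11.5 the 2 called genes became 1 without a filter, 5 with the replicate block, 4 with the covariate and 0 by limma without small RNA genes (385 at an unadjusted p under 0.05), and 2 to 17 without 1 library. The cause was not tested, except that both called genes are small RNA genes. In females the count was 3095 with the covariate and 4306 to 5424 without 1 library, in MIR against MC 1274 with the covariate, 3271 without MIR replicates 1 and 3 and 6171 to 8169 without 1 library, and between the sexes 5514 to 6941 without 1 library. For the difference between the female and male changes it was 557 with a filter at an FPKM of 5, where fewer genes were tested, 3763 with library weights, 198 without MIR replicates 1 and 3, where fewer samples were left, 8702 with the male codes turned and 463 to 2490 without 1 library. For the other counts the cause was not tested. Library weights did not reach their convergence tolerance at E13.5. Where 1 library was left in a group, it was assumed to vary like the other groups. Under the other alternatives the counts of all called genes stayed within 1.5 times, whereas list counts moved by more in 45 cases in females (351 did not), 61 in MIR against MC (395 did not), 68 between the sexes (553 did not) and 69 for the difference (231 did not), over all alternatives. At E13.5 replicate numbers did not pair the samples (same-number r -0.0358, -0.0331 and -0.0912 in females and -0.218, -0.149 and -0.0204 in males). At E11.5 the same-number r were 0.156 and 0.246 and the others -0.246 to 0.071, and 2 pairs do not settle it; with the block 859 genes there had an unadjusted p under 0.05, against 358. With the block, 11 meiosis genes were lower in females, against 6, and the counts were 5842, 7689, 6457 and 1005 at E13.5. Of 103 list tests, camera called 49 with the preset correlation and 0 with an estimated correlation, and fry called 46. With the covariate, estimates changed sign without passing the test in MIR against MC for Dazl (0.034, adjusted p = 0.929), Ddx4 (0.0027, 0.993), Sycp3 (0.58, 0.204) and Pmaip1 (0.64, 0.2), and in female against male for Bst2 (0.069, 0.678). In female against male they changed sign and passed for Mdm2 (-0.50, 0.000502), Ddx4 (-0.32, 0.00782) and Dazl (-0.37, 0.0232), none of which had passed before. The cause was not tested. With the male codes turned, the sign of the male change turns by construction, and the differences became Hsd17b3 4.66, Tesc 4.55, Amh 4.88, Ptgds 4.95, Aard 4.18, AU015836 3.004, Dhh 4.99, Cited1 2.98, Nt5e 3.999, Col9a3 5.20, Cbln4 3.26, Cyp26b1 3.55, Id1 2.50, Vim 5.24, Alas2 2.14, Postn 3.24, Id2 2.49, Perp 3.48, Hist1h1c 3.07, Ddx3y 1.23, Fut4 1.40, Ercc5 3.11, Scarb1 0.25, Kdm5d 0.57, Ccng1 4.85, Cdkn1a 3.09, Eda2r 3.82, Zmat3 2.80, Phlda3 4.69, Rec8 1.27, Trp53inp1 2.12, Bbc3 2.44, Nanog -2.46, Ddx4 -1.66, Eif2s3y -0.45, Dazl -1.70, Sycp3 -1.13, Pou5f1 -1.63, Hist1h3c -1.44, Isg15 -0.64, Ifitm1 -1.22, Nodal -0.035, Pou6f1 -1.21, Lefty1 -1.20, Nanos2 -1.54, Bnc2 -1.63. Among single genes named, calls were lost in 53 and gained in 4 of the female values under alternatives, against 1855 that stayed, and in 94 and 3 against 1970 (MIR against MC), 48 and 13 against 2184 (sexes), 89 and 20 against 1423 (difference) and 1 and 2 against 491 (E11.5). Fits of only the compared groups gave no other value for the sexes, their difference and E11.5, and DESeq2 was not run. Estimated depth was 14.6 to 21 M fragments at E11.5 and 13.6 to 26.8 M at E13.5. The share of simulated 2-fold changes recovered was 47.8% at E11.5, 79.1% in females and 41.8% for the difference, and how far depth limits it was not tested.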

Other observations

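The values here were chosen after the results were seen, and no further test was run on them. The genes here rose in irradiated females and had lower means in MIR than in MC (for Mest the male difference did not pass, adjusted p = 0.0507), so that the directions are opposite if MIR is the irradiated male set and the same if MC is, as titles and condition entries state. Mest, an imprinted gene, was at 118 ± 50 FPKM in irradiated and 16.8 ± 1.75 in non-irradiated females, and at 37.3 ± 9.54 in MIR and 56.3 ± 9.27 in MC (SD, n = 3 each). Enpp2, which makes lysophosphatidic acid, was at 9.42 ± 5.09 and 1.09 ± 0.257 FPKM in females and at 8.19 ± 0.543 and 19.9 ± 3.07 in MIR and MC. Gng13, a G protein subunit gene, was at 147.5 ± 43.8 and 27.8 ± 3.12 FPKM in females and at 34.7 ± 13.3 and 74.7 ± 11.7 in MIR and MC.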
